A study of Homo sapiens with 8 samples.

How the data were processed

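Chromatin immunoprecipitation followed by sequencing measured 2 histone marks in HAP1 cells, a near-haploid human line derived from the chronic myeloid leukaemia line KBM-7. H2AK119ub is histone H2A monoubiquitinated on a lysine, written by RING1A and RING1B, the E3 ligases of Polycomb repressive complex 1 (PRC1). H3K27me3 is histone H3 trimethylated on lysine 27, written by Polycomb repressive complex 2 (PRC2). Each mark was profiled in wild-type cells and in cells edited to lack RING1A and RING1B, called double knockout here, which makes 4 groups of 2 libraries. The labels' protocols call the samples biological duplicates and describe clones grown from sorted cells. How many knockout clones entered the libraries is not given in the sources used here, so the p-values measure the spread between these cultures and not between clones. For H3K27me3 the sample labels and the written protocol name different antibodies, and which was used in HAP1 is left open. The protocol describes fly S2 chromatin added as a reference genome, but states this for another cell line.

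The submitters' processing notes name Bowtie2, SAMtools, Picard, bedtools, deepTools and the human build hg19, without versions. How the regions were called, and from which libraries, is not given in the sources used here. The values used were the authors' normalized count per region and library, a score in whole numbers that, per the file headers, had already been normalized. The method of that normalization is not given in the sources used here, so a difference in level between libraries rests on it. The authors' deposited log2 columns equalled log2(normalized count + 0.5) to within 4.999e-09, and their log2 fold changes were the knockout mean minus the wild-type mean of those values. The p-value columns deposited by the authors matched an equal-variance two-sided test on these log2 values, with no adjustment, and 2 cells of the H2AK119ub column held no value. The table held all 34703 regions whatever their fold change or p. Starts in the file count from 0, and 1 was added to starts and ends, so that positions are given 1-based on hg19.

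Because the values were normalized, the count-model tests planned before the data were examined were replaced by the planned fallback, limma 3.58.1 in R 4.3.3 on log2(normalized count + 1), with the mean-variance trend and Benjamini-Hochberg adjustment at 0.05. No further scaling was applied. Fold changes are knockout minus wild type on the log2(normalized count + 1) scale, which understates changes of low regions. A region was tested for a mark when at least 2 of the libraries in the fit reached a normalized count of 10 and the sum was at least 15. This left 23700 regions for H2AK119ub, 32209 for H3K27me3 and 33127 for the fit of all 8 libraries that tested whether the knockout effect differed between the marks. limma moderates each region's spread with a prior, whose degrees of freedom were 1.10 for H2AK119ub, 107 for H3K27me3 and 4.88 for all libraries. The very small adjusted p-values of H3K27me3 therefore rest on a spread shared across regions more than on each region's own replicates. Simulated data had 200 changed regions, divided equally between 2-fold and 4-fold, and all others at the wild-type level in both genotypes. The H2AK119ub step (27281 regions) recovered 21 of 98 tested 2-fold changes (21.4%) and 78 of 92 tested 4-fold changes (84.8%). The H3K27me3 step (30811 regions) recovered 45 of 99 (45.5%) and 85 of 98 (86.7%), with 0 false calls in either step. The dispersion, the spread beyond counting noise, was set to 0.00497 for H2AK119ub and 0.001 for H3K27me3, the lowest value allowed. The simulation covers neither knockout H2AK119ub values near 0 nor changes in most regions. Its recovery and false calls therefore do not carry over to the fits below.

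The depth of the libraries is unknown, since only values over the regions were used. The total normalized count over the regions stands in for it and ran from 17159 to 3788824. Counting noise and counting error here and below take the normalized counts as read counts. In the knockout H2AK119ub libraries most regions were at 0, and the pair differed by no more than counting noise, with a spread 0.992 times that noise. The wild-type H2AK119ub pair thinned to the same totals gave 1.01, so the knockout libraries were kept as separate samples.

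Regions named in the text followed a rule fixed before the data were examined. For each mark these were the 6 largest falls and the 6 largest rises by log2 fold change, among called regions with a mean value above the median of tested regions and both knockout libraries beyond both wild-type libraries. Other regions are said to have been chosen after their values were seen. The regions carry no gene names, and an hg19 gene annotation was not used here. Regions are therefore given by position, and 15 gene lists fixed before the data were examined were not applied. For the same reason the knocked-out genes were not located among the regions, and the labels were not checked on them.

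Regions were also ranked into 10 equal density bins, numbered from 1 (least) to 10 (most), by the mean wild-type density (normalized count per kb) of the other mark, so that the ranking libraries took no part in the fold change. Bins carry the median change, with the value for each knockout library, and no p across regions. Totals and shares per library were compared by two-sided exact permutation tests, for which 2 against 2 libraries cannot give a p below 0.333. Alternatives covered scaling between libraries (TMM factors, median-of-ratios factors and column totals, each calculated directly), filters, pseudocounts of 0.1, 0.5 and 10, a fold threshold of 1.5 within the test, autosomes only, all libraries in 1 fit, the replicate number as a block, and leaving out each library. Descriptive values were calculated in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots were drawn with matplotlib 3.10.9.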

Results

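H2AK119ub and H3K27me3 were profiled by ChIP-seq in wild-type and RING1A/B double-knockout HAP1 cells, with 2 libraries for each mark and genotype. The design asks what becomes of the mark written by PRC1, and of the mark written by PRC2, in cells without the PRC1 ligases. The values were normalized counts over 34703 regions that did not overlap, on 23 chromosomes (the autosomes and X). The regions covered 459.8 Mb of hg19. Their median width was 6 kb, with 10th and 90th percentiles of 2 kb and 29.8 kb, and the widest spanned 643 kb. The total normalized count was 1575661 and 1866278 in the wild-type H2AK119ub libraries, 17159 and 20938 in the knockout H2AK119ub libraries, 2393140 and 2456126 in the wild-type H3K27me3 libraries, and 3788824 and 3224813 in the knockout H3K27me3 libraries. Taking normalized counts as read counts, counting error alone would give a coefficient of variation between 16.7% and 23.6% at the median region. This range covers the wild-type libraries and the knockout H3K27me3 libraries.

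On the values as deposited, H2AK119ub was lost almost completely from the regions in the knockout. The size of this loss rests on the authors' normalization, and the depth of the libraries is unknown. The total fell from 1721000 ± 205500 (SD, n = 2) in wild type to 19050 ± 2672 (SD, n = 2), which is 1.11% of the wild-type level, or between 0.919% and 1.33% for the 4 pairs of libraries. Averaged over the covered length, the density fell from 3.74 to 0.0414 normalized counts per kb. In the knockout libraries 24902 regions (71.8%) and 23507 regions (67.7%) were at 0, against 131 and 34 regions in wild type. The knockout and wild-type totals did not overlap, and the exact permutation p was 0.333, the smallest that 2 against 2 libraries allow.

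**Figure D1:**
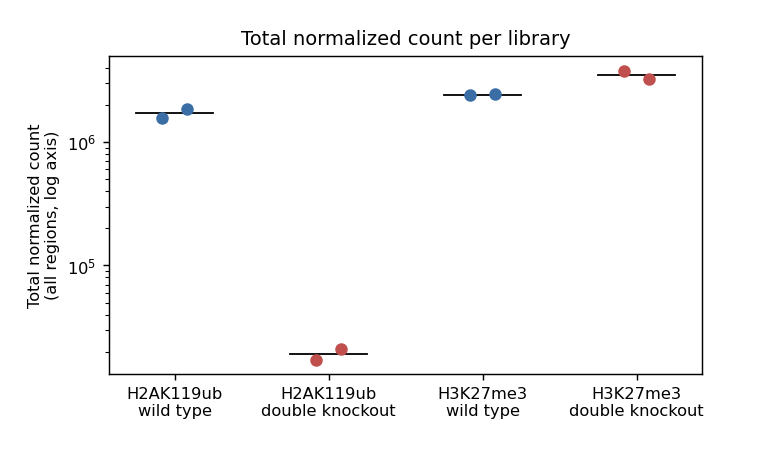
Total normalized count over all regions (log axis) for each of the 8 libraries, by mark and genotype; points are libraries and lines are means of 2. The knockout H2AK119ub libraries lie at 17159 and 20938, and the wild-type ones at 1575661 and 1866278.

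Region by region, limma with Benjamini-Hochberg adjustment called 23699 of 23700 tested regions lower in H2AK119ub and 0 higher, and at an unadjusted p under 0.05 there were also 0 higher. The median log2 fold change was -4.74, with 10th and 90th percentiles of -6.15 and -3.68. These values are bounded by the many knockout values at 0, so they follow the wild-type level of a region. The region that was not called, on chromosome 2 from 107194601 to 107199000, was chosen after its values were seen. It had 12 and 23 normalized counts in wild type and 0 and 4 in the knockout (adjusted p = 0.0572, limma). With knockout values this low, most regions passed the filter through their wild-type values, which favours lower calls. Without the filter, 33846 of 34701 regions were called lower and 0 higher. In the authors' deposited table, 30992 of all 34703 regions had a log2 fold change below -1 with p under 0.05, and 0 had one above 1. Without wild-type replicate 1 the test called 12398 regions lower, and without wild-type replicate 2 it called 12377, with median log2 fold changes of -4.91 and -4.60. In these fits the prior almost vanished (0.0686 and 0.0689 degrees of freedom), and calls followed whether the 2 knockout values of a region were equal. All 12140 regions with equal values were called, 10089 of them at 0 in both, and 258 and 237 of the 11560 others, so the lower counts say little about the loss itself. Scaling the libraries to each other removes most of the loss by construction, and then 10154 to 10815 regions were called lower and 66 to 437 higher, with a median log2 fold change of -1.59 under TMM factors. A knockout value of 0 stays 0 under any such factor, as in the 10089 regions at 0 in both knockout libraries. How many of the lower calls were those regions was not counted, so these calls do not measure a loss that withstands scaling.

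The 6 regions with the largest H2AK119ub falls by the fixed rule lay on chromosomes 6, 12, 14, 17 and 22. On chromosome 17, the region from 46663001 to 46721600 (58.6 kb) fell from 833.5 ± 26.2 (SD, n = 2) normalized counts to 1.5 ± 0.707 (SD, n = 2). On chromosome 14, the region from 61932601 to 62044600 (112 kb) fell from 1242.5 ± 92.6 (SD, n = 2) to 3.5 ± 3.54 (SD, n = 2). On chromosome 22, the region from 50054401 to 50133400 (79 kb) fell from 585.5 ± 46 (SD, n = 2) to 1.0 ± 1.41 (SD, n = 2). The others were listed at 0 in both knockout libraries. These were chromosome 12 from 54428001 to 54467800, with 473 and 544 normalized counts in wild type, chromosome 6 from 106430601 to 106480800, with 285 and 375, and chromosome 17 from 48638201 to 48667600, with 308 and 318. Adjusted p-values (limma) ran from 0.000204 to 0.00188. H3K27me3 fell in 5 of the 6, for example from 557 ± 43.8 (SD, n = 2) to 51.5 ± 6.36 (SD, n = 2) in the chromosome 12 region and from 1303.5 ± 3.54 (SD, n = 2) to 94.5 ± 6.36 (SD, n = 2) in the chromosome 14 region. In the chromosome 22 region it was 1045.5 ± 75.7 (SD, n = 2) in wild type and 1432.0 ± 100.4 (SD, n = 2) in the knockout (log2 fold change 0.45, adjusted p = 0.00427, limma). The H2AK119ub calls of the chromosome 14 and chromosome 22 regions were lost without wild-type replicate 1 (adjusted p = 0.132 and 0.127, limma) and without wild-type replicate 2 (0.138 and 0.132), and under each scaling. The larger chromosome 17 region was not called without wild-type replicate 1 (0.0583) or replicate 2 (0.0588). The knockout values differ in these 3 regions, and their log2 fold changes without a wild-type library ran from -8.48 to -8.30.

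H3K27me3 changed in both directions in the knockout, with more regions higher than lower. Of 32209 tested regions, 15228 (47.3%) rose, 7338 (22.8%) fell and 9643 (29.9%) were not called (limma, Benjamini-Hochberg adjustment). The rise exceeded 1 on the log2 scale in 10621 regions and the fall in 6183. The median log2 fold change was 0.58, with 10th and 90th percentiles of -1.95 and 1.56 and a median SE of 0.32. Summed over the regions, H3K27me3 was 2425000 ± 44540 (SD, n = 2) normalized counts in wild type and 3507000 ± 398800 (SD, n = 2) in the knockout, 1.45 times as high, or 1.31 to 1.58 times for pairs of libraries (exact permutation p = 0.333, the smallest possible). The mean density over the covered length was 5.27 and 7.63 normalized counts per kb. The excess of rises rests on the authors' normalization. Rises made up 67.5% of the calls on the values as deposited, 46.3% with TMM factors (9470 higher, 10977 lower), 45.1% with median-of-ratios factors and 46.5% with column totals, and TMM factors brought the median log2 fold change to 0.05. With 3 libraries the prior degrees of freedom fell from 107 to 1.40 without either wild-type library and to 1.09 without either knockout library. Without wild-type replicate 1 or replicate 2 the smallest adjusted p-values of all regions (limma) were 0.0836 and 0.0811, so 0 regions were called, while the median log2 fold change was 0.55 and 0.58. At an unadjusted p under 0.05 those fits held 4870 lower and 10015 higher regions, and 4836 and 10266. Without knockout replicate 1 there were 4262 lower and 4467 higher calls (median log2 fold change 0.43, smallest adjusted p 0.0417, limma), and without knockout replicate 2 there were 4075 and 8148 (0.69, 0.0373).

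The largest H3K27me3 falls left almost none of the mark. On chromosome X, the region from 25024601 to 25044600 (20 kb) fell 49.6-fold, from 248 ± 19.8 (SD, n = 2) normalized counts to 5 ± 2.83 (SD, n = 2), with an adjusted p of 2.24e-31 (limma). On chromosome 1, the region from 202611601 to 202635600 (24 kb) fell 31.8-fold, from 333.5 ± 16.3 (SD, n = 2) to 10.5 ± 0.707 (SD, n = 2). On chromosome 9, the region from 94316401 to 94335600 (19.2 kb) fell from 155.5 ± 9.19 (SD, n = 2) to 4.5 ± 0.707 (SD, n = 2). Shorter regions with falls of this size were chromosome 13 from 100643001 to 100650000 (106 ± 2.83 to 2.5 ± 0.707, SD, n = 2), chromosome 22 from 42308401 to 42314600 (87.5 ± 13.4 to 2 ± 0, SD, n = 2) and chromosome 3 from 76696201 to 76705000 (71 ± 1.41 to 1.5 ± 2.12, SD, n = 2). All 6 carried H2AK119ub in wild type, between 43 and 306 normalized counts on average, and at most 2 in the knockout. The largest rises were in regions with little H3K27me3 in wild type. On chromosome 7, the region from 14620601 to 14631800 (11.2 kb) rose 11.6-fold, from 8 ± 4.24 (SD, n = 2) to 93 ± 5.66 (SD, n = 2), with an adjusted p of 8.88e-16 (limma). On chromosome 6, neighbouring regions from 55755401 to 55767800 and from 55794001 to 55804600 rose 9.12-fold and 10.9-fold. On chromosome 2, the region from 84460401 to 84475200 (14.8 kb) rose 9.18-fold, from 17 ± 1.41 (SD, n = 2) to 156 ± 7.07 (SD, n = 2). The regions on chromosome 12 from 124777801 to 124784800 and on chromosome 9 from 7464401 to 7473800 rose 9.95-fold and 8.2-fold. Wild-type H2AK119ub in these 6 ran from 10.5 to 62.5 normalized counts. These counts are per region and not per kb. The chromosome 12 rise, with 62.5 in 7 kb, was denser in wild-type H2AK119ub than the chromosome 3 fall, with 43 in 8.8 kb. The chromosome 12 rise therefore runs against the order by density given below. Without either wild-type library no region at all was called, so the lack of calls for these 12 says nothing about them, and their log2 fold changes ran from -5.54 to -4.72 for the falls and from 2.43 to 3.97 for the rises. The rises on chromosome 7 and on chromosome 9 were not called (limma, Benjamini-Hochberg adjustment) without knockout replicate 1 (0.0678 and 0.105) or replicate 2 (0.0588 and 0.0805), nor that on chromosome 12 without knockout replicate 1 (0.0574). In these fits the smallest adjusted p-values of all regions were close to the limit too, and the log2 fold changes of these rises ran from 2.83 to 3.53.

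**Figure D2:**
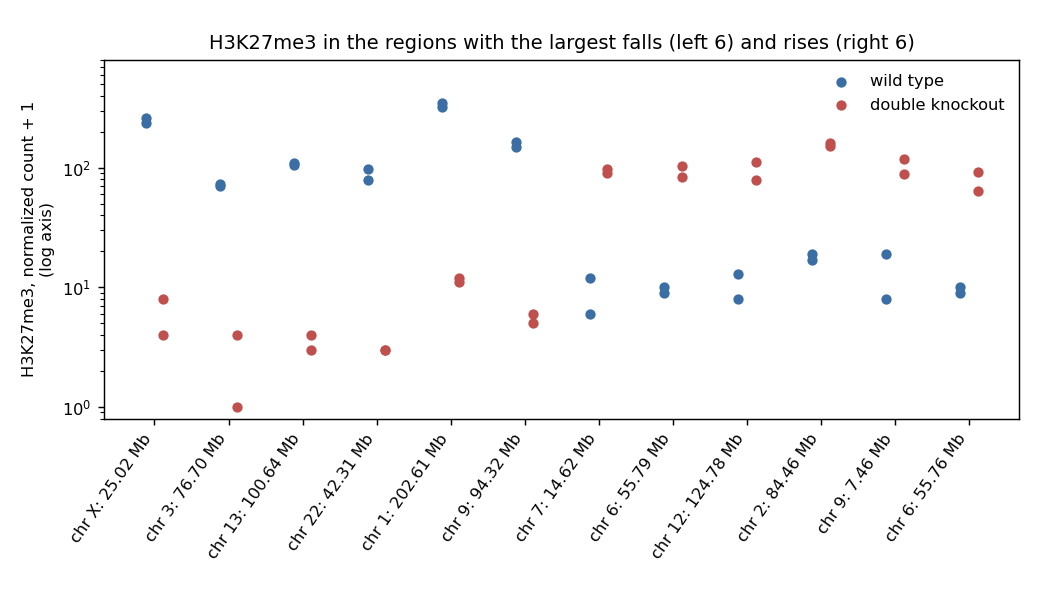
H3K27me3 (normalized count + 1, log axis) in each library for the 6 regions with the largest falls and the 6 with the largest rises; points are libraries, and positions are region starts in Mb. By the rule that chose the regions, the wild-type and knockout points do not overlap in any of them. They run from 234 and 262 against 7 and 3 normalized counts in the chromosome X region to 5 and 11 against 97 and 89 in the chromosome 7 region.

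The direction of the H3K27me3 change went with the wild-type density of H2AK119ub. The regions were ranked by wild-type H2AK119ub per kb into 10 equal density bins. In bin 1, with the least H2AK119ub, the median log2 change was 1.27 (1.45 and 1.12 for the knockout libraries), and 76.8% of tested regions rose and 2.67% fell. In bin 10, with the most, the median was -1.21 (-1.05 and -1.27), and 60.6% fell and 7.62% rose. The median decreased at each step between them and, on the values as deposited, crossed 0 between bin 7 (0.07) and bin 8 (-0.39). Wild-type H3K27me3 increased with H2AK119ub from 2.79 ± 0.0109 (SD, n = 2) normalized counts per kb in bin 1 to 9.54 ± 0.224 (SD, n = 2) in bin 10. In the knockout the same bins held 7.06 ± 1.01 (SD, n = 2) and 6.19 ± 0.533 (SD, n = 2). Wild-type H3K27me3 takes part in the change and was not held equal between bins, so the order may follow its level as well. Across the 34703 regions, which are not independent replicates, Spearman's rho between wild-type H2AK119ub density and the H3K27me3 change was -0.600. Wild-type and knockout H3K27me3 densities had a rho of -0.314. With TMM factors the medians of bins 1 and 10 were 0.82 and -1.65. The crossing point depends on scaling, since 7 bin medians lay above 0 as deposited and 5 with TMM factors or column totals. Ranking by the H2AK119ub of the whole region rather than per kb places regions by width as well as density and gave medians of 0.86 and 0.48, so the negative median of bin 10 belongs to the ranking by density. The regions were then split into 5 equal bins by width, and each of these into 5 by density. In each width bin the lowest density bin had a higher median than the highest. These medians were 0.94 and -1.38 in the narrowest regions (median 2 kb) and 1.27 and -0.52 in the widest (median 29.9 kb).

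**Figure D3:**
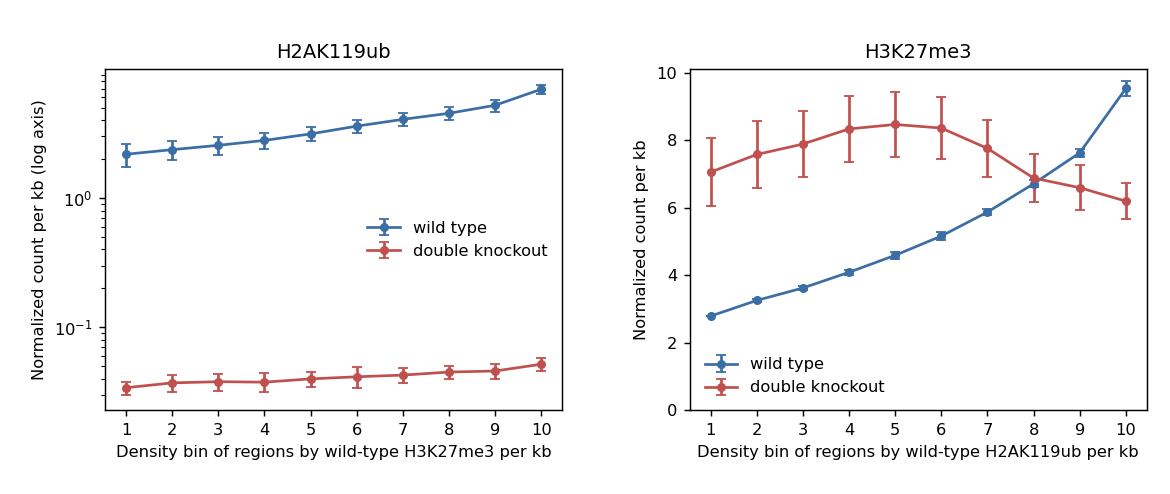
Mean density (normalized count per kb) of H2AK119ub (left, log axis) and H3K27me3 (right) in 10 equal bins of the regions ranked by the wild-type density of the other mark; points are means and bars are SD of 2 libraries. Knockout H3K27me3 lies above wild type in bin 1 (7.06 against 2.79) and below it in bin 10 (6.19 against 9.54).

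The H2AK119ub that was left in the knockout differed less between regions ranked by wild-type H3K27me3 density. In wild type the H2AK119ub density was 2.18 ± 0.437 (SD, n = 2) normalized counts per kb in bin 1, with the least H3K27me3, and 6.95 ± 0.588 (SD, n = 2) in bin 10. In the knockout these densities were 0.0341 ± 0.00388 (SD, n = 2) and 0.0517 ± 0.00558 (SD, n = 2), which is 1.56% and 0.745% of wild type. Bin 10 held 19.6% ± 0.686 (SD, n = 2) of the H2AK119ub count in wild type and 13.2% ± 0.430 (SD, n = 2) in the knockout, and 10.5% of the covered length. For H3K27me3, the bin of regions densest in wild-type H2AK119ub held 14.6% ± 0.0742 (SD, n = 2) of the count in wild type and 6.58% ± 0.183 (SD, n = 2) in the knockout, on 8.09% of the length. In each mark the knockout libraries lay below both wild-type libraries (exact permutation p = 0.333, the smallest possible). These shares do not depend on scaling between libraries.

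H3K27me3 changes also differed with the width of a region and between chromosomes. Over 5 equal bins by width, the median log2 change was -0.45 (-0.29 and -0.55 for the knockout libraries) in the narrowest regions and 0.83 (0.95 and 0.71) in the widest, where 68.2% of tested regions rose and 17.2% fell. With TMM factors these medians were -0.88 and 0.36. Among chromosomes, the median was highest on X at 1.00 (1.15 and 0.85), where 63.2% of tested regions rose, followed by chromosomes 4 at 0.86 and 20 at 0.85. It was lowest on chromosomes 1 at -0.01, 15 at -0.03 and 22 at -0.08. On chromosome 22, 120 of 357 tested regions fell and 125 rose, and the summed knockout density was 1.83 times that of wild type. The sign of these medians depends on scaling: 20 of 23 chromosome medians lay above 0 on the values as deposited, 15 with TMM factors and 10 with column totals. The median on X was the highest under each, at 0.55 with TMM factors and 0.50 with column totals. Residual H2AK119ub ran from 0.943% of wild type on chromosome 1 to 1.36% on X. The higher share on X goes with the lowest wild-type density of all chromosomes (2.74 normalized counts per kb, against 4.49 on chromosome 1). Its knockout density was also the lowest (0.0372, against 0.0423 on chromosome 1).

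**Figure D4:**
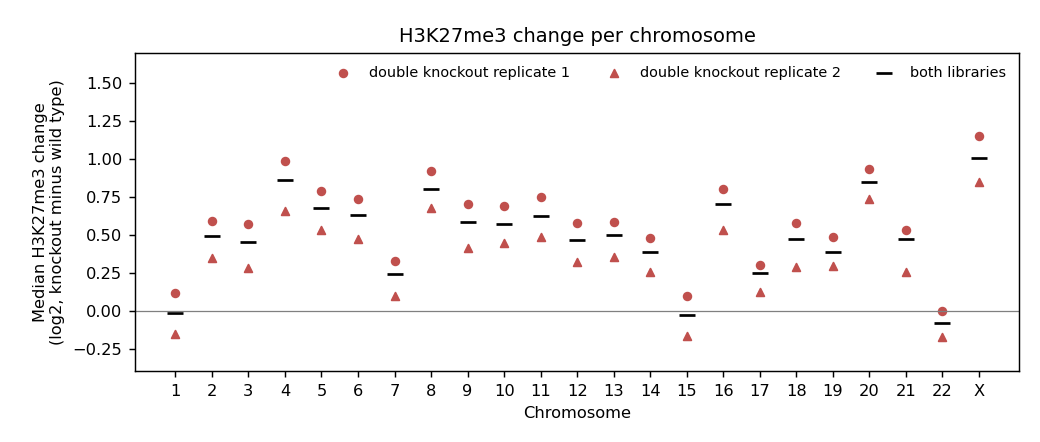
Median log2 change of H3K27me3 (knockout minus wild type) over the regions of each chromosome; circles and triangles are the knockout libraries against the wild-type mean, and bars use both. Chromosome X has the highest median (1.00) and chromosome 22 the lowest (-0.08) on the values as deposited, and 15 of the 23 medians lie above 0 with TMM factors.

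Regions changing in the same direction lay next to each other. The longest run of consecutive regions called lower in H3K27me3 held 19 regions on chromosome 15 from 65603001 to 67258400 (1.66 Mb), where the summed count fell from 8862 ± 137.2 (SD, n = 2) to 1666 ± 311.8 (SD, n = 2). Most of this summed fall came from 1 region of 360.4 kb, from 66222201 to 66582600, which fell from 6309 ± 134.4 (SD, n = 2) to 716.5 ± 159.1 (SD, n = 2). The limits of the run follow the calls. The region just before it was also lower in the knockout (3.33 and 2.92 normalized counts per kb, against 5.83 and 6.25 in wild type). The region just after it was not (13.07 and 11.04, against 11.14 and 9.39). The longest run called higher held 39 regions on chromosome 12 from 117628401 to 120104800 (2.48 Mb), where it rose 2.77-fold, from 5810 ± 212.1 (SD, n = 2) to 16080 ± 1570 (SD, n = 2). In 200 shuffles of the calls within chromosomes the longest runs reached 11 regions called lower and 22 called higher. Shuffling treats regions as independent, but neighbours lie as little as 5 kb apart and may be parts of a broad domain. The longer observed runs therefore say only that neighbours changed together. These runs were chosen after their values were seen.

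**Figure D5:**
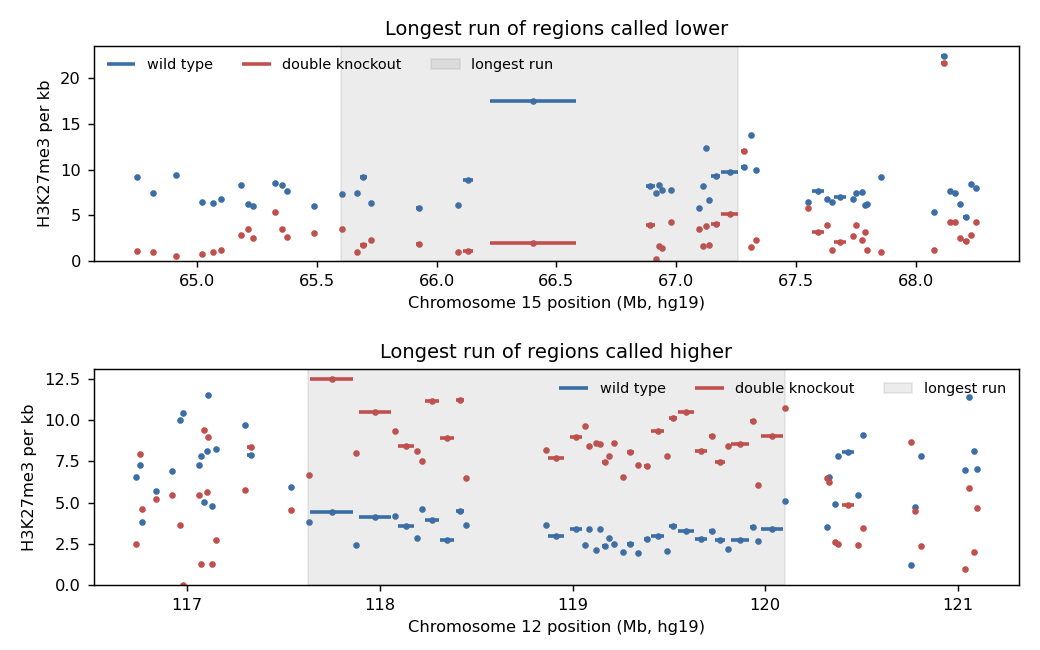
H3K27me3 density (normalized count per kb, mean of 2 libraries) of each region in the longest run called lower on chromosome 15 and the longest run called higher on chromosome 12, with the regions around them; lines span the regions, dots mark their centres and shading marks the runs. In the shaded parts the summed knockout count is 0.188 and 2.77 times that of wild type. The summed fall on chromosome 15 comes mostly from 1 region of 360.4 kb.

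Of the 23324 regions tested for both marks, 11220 (48.1%) lost H2AK119ub and gained H3K27me3, 6052 (25.9%) lost both, and 6051 (25.9%) lost H2AK119ub without a call for H3K27me3. The remaining region is the uncalled chromosome 2 region above. H2AK119ub was called lower in all the others, so this split restates the H3K27me3 calls and rests on the same normalization. Of all 32209 regions tested for H3K27me3, 47.3% rose and 22.8% fell. In the fit of all 8 libraries, the knockout effect on H2AK119ub was lower than that on H3K27me3 in 31046 of 33127 tested regions and higher in 1 (limma, Benjamini-Hochberg adjustment). This difference is set mainly by the loss of H2AK119ub nearly everywhere, with a median of -4.56 on the log2 scale. With TMM factors the counts were 15750 and 592. The count of higher regions was 0 without either knockout H2AK119ub library or either wild-type H3K27me3 library, also at an unadjusted p under 0.05, 7 without wild-type H2AK119ub replicate 2, and 6 and 4 without knockout H3K27me3 replicates 1 and 2.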

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

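The test of a scaling factor per library was chosen after the result was seen. A difference between the marks in the same contrast drew attention: the knockout effect on H2AK119ub was lower than that on H3K27me3 in 31046 regions and higher in 1 (limma, all 8 libraries). That region lies on chromosome 12 from 83595201 to 83599000 and was chosen after its values were seen. It had 17 and 24 normalized counts of H3K27me3 in wild type and 0 and 0 in the knockout, and 5 and 18 of H2AK119ub in wild type and 1 and 1 in the knockout. Without either knockout H2AK119ub library or either wild-type H3K27me3 library limma called 0 regions higher, also at an unadjusted p under 0.05, and it called 7 without wild-type H2AK119ub replicate 2 and 6 and 4 without knockout H3K27me3 replicates 1 and 2.

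The pattern beneath it is that H3K27me3 fell in regions dense in wild-type H2AK119ub and rose in sparse ones. A scaling factor common to a library shifts all density bins alike, but the median of bin 1 exceeded that of bin 10 by 2.51 and 2.39 on the log2 scale in knockout replicates 1 and 2. Regions selected by their level in 1 genotype would give such a pattern by regression. Among the 17351 regions above the median of wild-type H3K27me3 density, the lowest and highest of 5 H2AK119ub density bins differed by 1.12 and 1.08. Their medians were -0.126 and -1.26, so the median of the lowest bin showed no rise there. Wild-type H3K27me3 was not held equal between these bins, and over all regions it correlated with wild-type H2AK119ub density (Spearman's rho 0.671). The difference therefore cannot tell selection from other causes, and selection stays open. Width did not account for the pattern. In each of the 5 width bins and both knockout libraries, the lowest and highest of 5 H2AK119ub density bins differed by at least 1.76. The biological difference in the design, the loss of RING1A/B, stays open as untested, as do other differences between the wild-type and knockout cells, such as those of a clone.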

How the results depend on the processing

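Chosen after seeing the data were the authors' own test and pseudocount, the limit of 1 on the log2 fold change, and the pseudocounts and autosomes for the difference between marks. H2AK119ub: lower calls were 10815 with TMM factors, 10409 with median-of-ratios factors and 10154 with column totals, and higher calls 66, 177 and 437, since these scalings equalize levels by construction. Leaving out 1 library gave 12377 to 23686 lower calls, and without a wild-type library these were mostly the 12140 regions with equal knockout values. H3K27me3: higher calls were 9470, 9163 and 9516 under those scalings, and lower calls 11141 with median-of-ratios factors. The stricter filter (fewer regions tested) gave 3196 lower calls. The fold threshold of 1.5 gave 4826 lower and 7579 higher calls. The authors' test gave 4360 and 7306, over all 34703 regions, with a pseudocount of 0.5, unadjusted p under 0.05 and a log2 fold change beyond 1. Leaving out 1 library gave 0 to 4262 lower and 0 to 8148 higher calls, with the lone sample assumed to vary like the other group. The 0 arose without either wild-type library, where the smallest adjusted p of all regions was 0.0836 and 0.0811 (limma, prior degrees of freedom 1.40 against 107), and the median log2 fold change there was 0.55 and 0.58. Difference between marks: lower calls were 15750, 14724 and 14272 under the scalings and 17225 with the stricter filter. Higher calls were 592, 954 and 1406 under the scalings, 0 with the stricter filter (limma, also 0 at an unadjusted p under 0.05) and 28 with a pseudocount of 10, and 0 to 7 with 1 library left out. Median H3K27me3 changes of density bins 1 and 10 were 0.82 and -1.65 with TMM factors, 0.78 and -1.69 with column totals, and 0.86 and 0.48 when not ranked per kb, where bin 10 changed sign. The highest of 5 bins was at -1.03. For H2AK119ub they were -0.98 and -1.66, -0.66 and -1.01, -2.66 and -6.11, and -3.46 and -4.53 in 5 bins. With 1 library left out they ran from -3.46 to -3.09 and from -4.95 to -4.76. Over filtered regions alone the shares of bin 10 were 18.8% and 12.5% for H2AK119ub and 15.3% and 6.83% for H3K27me3 (wild type, knockout). With the replicate block, calls were 23700 lower for H2AK119ub, 7279 lower and 15015 higher for H3K27me3, and 31195 and 1 for the difference. Same-numbered libraries did not deviate together (correlations -0.03 to 0.023), so no pairing by number was seen. With most knockout H2AK119ub values at 0, the correlations with those libraries could hardly show a pairing. The block changed no call count by over 1.5 times. Of 323 alternative values for the named regions, 281 were still called in the same direction, 42 were not called and 0 reversed. Most of those not called came with 1 library left out, chiefly in the fits that called no region. The others were 6 under a scaling and the H3K27me3 fall on chromosome 3 under the authors' test. Where no cause is given above, the cause was not tested. The count-model test, the gene list tests and the shares of gene lists were not run, because the values are normalized and the regions carry no gene names. Regions with few counts limit the H2AK119ub fold changes, since most knockout values are 0.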

Other observations

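Neighbouring regions changed in H3K27me3 by similar amounts. For 34680 pairs of consecutive regions the correlation of their log2 changes was 0.577 and 0.576 in the knockout libraries, and it decreased from 0.757 at gaps of 5 to 10 kb to 0.249 at gaps above 200 kb (both libraries averaged). After subtracting the median change of each region's H2AK119ub density bin (of 10) it was 0.459 and 0.467. Pairs of regions are not independent, so no p is given. The region with the most H2AK119ub in wild type, on chromosome 15 from 66222201 to 66582600 (360.4 kb), was chosen after its values were seen. It lies in the longest run called lower in H3K27me3. Its rank is by count and not per kb. The region also lies in the chromosome 15 segment treated below, where wild-type H2AK119ub density was 1.99 and 1.89 times that of other chromosomes. Whether DNA copy number raised its level was not tested. Its H2AK119ub fell from 5349 ± 323.9 (SD, n = 2) normalized counts to 44 ± 7.07 (SD, n = 2), and its H3K27me3 fell from 6309 ± 134.4 (SD, n = 2) to 716.5 ± 159.1 (SD, n = 2), which left 11.4%.

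The H2AK119ub left in the knockout was less concentrated than in wild type, and the tests below were chosen after this was seen. Uniform background as its whole source would give equal densities in density bins 1 and 10 by wild-type H3K27me3. The ratio of bin 10 to bin 1 was 1.53 (95% exact binomial interval 1.41 to 1.66) in knockout replicate 1 and 1.51 (1.40 to 1.63) in replicate 2, with intervals that cover counting error only. Carry-over of wild-type reads alone would give the wild-type ratio of 2.96 to 3.49, above both intervals. A mixture of background and carried-over or true H2AK119ub, or background that varies along the genome, may give such a ratio (1.53) and was not tested.

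Several of the highest knockout H2AK119ub values lay between 66 and 87 Mb of chromosome 15. HAP1 and its parent line are known to carry an extra copy of a segment of this chromosome, and the limits used, 61 and 90 Mb, come from that knowledge. In the 452 regions between them the knockout H2AK119ub density was 2.12 and 1.97 times that of the rest of the chromosome (replicates 1 and 2), which largely restates the first observation in the same libraries and gives no separate support to an extra copy. In the 140 regions of the segment outside 66 to 87 Mb, a test chosen after that ratio was seen, it was 1.95 (95% exact binomial interval 1.61 to 2.35) and 1.87 (1.58 to 2.22), in intervals that cover counting error only, so a second DNA copy in these near-haploid cells is a candidate explanation. Carry-over of wild-type H2AK119ub would raise the segment too and stays open, since the whole-segment ratio was 2.26 and 2.12 for wild-type H2AK119ub (for H3K27me3, 1.59 and 1.59 in wild type and 1.31 and 1.33 in the knockout).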
